A study of Mus musculus with 6 samples.

How the data were processed

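The series holds 6 Smart-seq2 libraries of leptotene and zygotene spermatocytes sorted from mouse testes at postnatal day 12, 3 from Srp68 SKO and 3 from wild type animals, per the labels. Per the labels' protocols, tubules were dissociated with collagenase and then trypsin, mRNA was reverse transcribed and cDNA amplified with a commercial whole-transcriptome kit, and sequencing libraries were made by transposase-based fragmentation. The submitters' processing notes name FastQC for read quality, Trim Galore 0.6.4 for trimming, HISAT2 2.0.5 for alignment and the mouse builds GRCm38 and mm10. The counting tool, its strand setting and the gene annotation used for counting are not given in the sources used here. The deposited table holds raw counts of reads per gene, as whole numbers that sum to a different total in each library, with no normalization by the authors. Its columns name the knockout libraries CKO where the labels write SKO, and each was assigned by genotype and replicate number, as the series has a single knockout group. The table lists 49584 gene identifiers, of which 25887 had a count in at least 1 library. GENCODE vM21 on GRCm38 supplied gene symbols, positions, exon lengths and transcript GC content for 49325 of them, and 259 were not in it. Smart-seq2 reads carry no molecular identifiers, so PCR copies cannot be told from separate molecules, and count floors cover counting error only. The kits described do not mark strand as far as the labels say, so reads from overlapping genes on opposite strands cannot be told apart here, and genes with pseudogene copies are uncertain.

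Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the genotype as group, which left 13474, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment over all tested genes and an adjusted p under 0.05 as the threshold. Log2 fold changes are SKO over wild type, and their standard errors were derived from the same fit. CPM values are TMM-scaled and given as mean ± SD of 3 libraries per genotype. The biological coefficient of variation was 0.304. Library measures were compared with two-sided exact permutation tests. Principal components and correlations used log2 CPM of the tested genes. A chi-square test on genes with a summed count of at least 20 asked whether replicates differed by more than sampling noise.

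The design, the 31 gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where stated. The lists covered SRP subunits and receptor, ER translocon and signal peptidase, SRP-independent targeting, N-glycosylation, ER chaperones, the integrated stress response, apoptosis, meiotic entry, synaptonemal complex, recombination, pachytene and spermatid markers, both kinds of spermatogonia, the piRNA pathway, the mitotic cell cycle, Sertoli, Leydig, myoid, macrophage, endothelial and erythroid markers, lysosome, cholesterol synthesis, proteasome, heat shock, immediate early and interferon-stimulated genes, ribosomal proteins, and nuclear-encoded and mitochondrially encoded subunits of oxidative phosphorylation. Some genes stand in more than 1 list. Lists were compared with all other tested genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 30 lists with enough tested members. With an estimated correlation 0 of the 30 lists passed in camera (8 at an unadjusted p under 0.05, smallest adjusted p = 0.174), while 10 passed with the preset correlation, 17 in fry, which tests whether a list moves in 1 direction on balance without comparing it with other genes, and 25 in fry's test for change in either direction. Named genes were Srp68, the 10 largest changes in each direction among called genes with separate groups, a mean of at least 5 CPM in the higher group and an established symbol, and up to 3 called members of each list by smallest p. Of 96 named genes, 26 had an exon overlap with another gene, and 4 over more than 20% of their exon length.

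Alternatives were DESeq2 size factors, upper-quartile scaling, library totals only, mitochondrial and ribosomal protein genes left out, no low-count filter, a filter of at least 5 CPM in 3 libraries, edgeR with robust fitting, DESeq2 1.42.0, limma-voom with and without sample weights, a replicate block, each library left out in turn, stricter thresholds, and camera with an estimated correlation or fry for the lists. A correction for GC content and length was added after the data were seen. It fitted a loess curve (span 0.3) of each library's log expression on transcript GC content and log exon length and used the fitted trends as offsets in edgeR, for the 99.8% of tested genes with a known GC content. A bootstrap over genes gave standard errors of medians. For the ribosomal list, 10000 random lists were drawn from its nearest protein-coding genes by GC content, exon length and mean expression. This was repeated with expression given 3 or 10 times the weight. Ribosomal protein and nuclear-encoded oxidative phosphorylation genes were left out of the genes drawn from. Proteins likely to need SRP were predicted from annotated coding sequences in Python 3.11.15, as those with a mean hydropathy of at least 2.2 over 9 residues within the first 35 residues, or of at least 1.6 over 19 residues elsewhere, excluding proteins whose only such segment ended within 50 residues of the C terminus. All 10 splits of the 6 libraries into groups of 3 were fitted.

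The pipeline was tested on simulated data. In simulated counts for the 13474 genes at the depth of these libraries, 100 randomly drawn genes were changed at each fold. There edgeR recovered 48% of 2-fold and 74% of 4-fold changes, with 3.17% false calls. With a simulated GC trend and no changed genes, 740 genes were called before and 0 after the correction.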

Results

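Poly(A) RNA was profiled in leptotene and zygotene spermatocytes, the germ cells of early meiotic prophase, which had been isolated by fluorescence-activated cell sorting from mouse testes at postnatal day 12. Libraries were made with Smart-seq2, a method that copies full-length cDNA from few cells and amplifies it by PCR. The 6 libraries comprised 3 labelled Srp68 SKO and 3 labelled wild type. Srp68 encodes a subunit of the signal recognition particle (SRP), the ribonucleoprotein that brings ribosomes translating secretory and membrane proteins to the endoplasmic reticulum (ER). The series title names Srp68 knockout, co-translational targeting and meiotic arrest, so the comparison asked which transcripts differed between SKO and wild type spermatocytes of this stage.

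The wild type libraries held 14.3, 15.4 and 14.3 M counts (mean 14.6 ± 0.638 M, SD, n = 3) and the Srp68 SKO libraries 12.7, 11.9 and 11.9 M (12.2 ± 0.493 M, SD, n = 3; two-sided exact permutation test, p = 0.1). With 3 libraries against 3, an exact permutation test cannot give a p below 0.1. At this depth, 3 counts corresponded to 0.195 to 0.253 CPM. Genes with at least 1 count numbered 18315 ± 234 in wild type and 18876 ± 441 in SKO libraries (exact permutation p = 0.2). The share of counts assigned to cytosolic ribosomal protein genes was 5.61 ± 0.254% in wild type and 8.42 ± 0.204% in SKO (exact permutation p = 0.1). Mitochondrially encoded genes took 4.30 ± 0.132% and 4.6 ± 0.551% (exact permutation p = 0.5), and X-linked genes 3.33 ± 0.0859% and 4.28 ± 0.122% (exact permutation p = 0.1). The 20 most abundant genes held 10.3 ± 0.328% of wild type and 11.8 ± 0.877% of SKO counts (exact permutation p = 0.1). The first principal component carried 46.4% of the variance, and correlations between libraries ran from 0.945 to 0.961 within a genotype and from 0.905 to 0.929 between genotypes. Replicates of a genotype differed by more than sampling noise (chi-square per degree of freedom 12.0 to 22.2), so none was taken as the same library deposited again; amplification of the same RNA could also exceed that noise. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

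Srp68 transcripts were lower in every SKO library than in every wild type library. Srp68 (ENSMUSG00000020780; GRCm38 chromosome 11, 116245166 to 116274217, minus strand, a protein-coding gene) had 337, 505 and 345 counts in wild type replicates 1 to 3 and 147, 70 and 72 in SKO replicates 1 to 3. In CPM, wild type replicates were at 21.7, 29.3 and 22.6 (24.5 ± 4.12, SD, n = 3) and SKO replicates at 12.1, 6.52 and 6.93 (8.51 ± 3.11, SD, n = 3). The SKO mean was 34.7% of the wild type mean, with a log2 fold change of −1.52 (SE 0.28) and an adjusted p of 0.00107 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact permutation p was 0.1, the smallest that 3 against 3 allows. The part of the gene that was removed is not given in the sources used here. Counts are per gene, so reads from exons outside a deleted part may remain in these values. The source of the counts left in the SKO libraries was not tested.

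Across the 13474 genes tested, 1901 were higher and 1937 lower in SKO spermatocytes, 28.5% of all tested genes. The steepest increases included amino acid transporters and enzymes of amino acid metabolism. Slc7a3, a cationic amino acid transporter, rose from 1.2 ± 1.26 to 62.2 ± 11.5 CPM (SD, n = 3 per genotype; edgeR adjusted p = 2.84e-06). Asns, asparagine synthetase, rose from 17.4 ± 5.78 to 158 ± 24.8 CPM (edgeR adjusted p = 9.09e-07). Slc7a11, the cystine transporter subunit, rose from 0.296 ± 0.359 to 22.6 ± 10.4 CPM (edgeR adjusted p = 1.16e-05). Chac1, which degrades glutathione, had 0 counts in the 3 wild type libraries and 299 in the 3 SKO libraries (8.89 ± 2.61 CPM). Against 3 counts over the wild type group, a floor of 0.0623 CPM that covers counting error only, it was at least 143-fold higher. The neutral amino acid transporter Slc1a4 (log2 fold change 5.73), Prodh2 (5.49), the mitochondrial alanine aminotransferase Gpt2 (5.23), the connexin gene Gja1 (3.78), the immediate early gene Fos (2.98) and Vldlr (2.65) completed the 10 largest increases taken by the naming rule. The steepest decreases were in Prr19, a partner of the cyclin-related protein Cntd1 in meiotic crossover formation (17.7 ± 8.28 to 0.406 ± 0.355 CPM; log2 fold change −5.38; edgeR adjusted p = 2.73e-05), and Ube2m, a conjugating enzyme of the ubiquitin-like protein NEDD8 (27.9 ± 4.01 to 0.837 ± 0.63 CPM; −5.01; 2.03e-06). Tom1 (log2 fold change −3.9), Als2cr12 (−3.67), the lysosomal exonuclease gene Pld3 (−3.65), Aes (−3.42), Ssbp4 (−3.22), Abo (−3.19), Gk2 (−3.18) and the RNA-binding protein gene Rbm38 (−3.17) followed. Of the tested genes, 5900 (43.8%) had every SKO library on one side of every wild type library, where chance gives 10%. Among the calls, 521 increases and 1060 decreases reached 2-fold, and 1669 increases and 1862 decreases were in protein-coding genes.

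The split between increases and decreases depended on the scaling between libraries. With library totals in place of TMM factors, 1010 genes were higher and 3168 lower, so that 24.2% of calls were increases in place of 49.5%, and the median log2 fold change of all tested genes moved from −0.03 to −0.29. Without SKO replicate 3, Gja1 lost its call (log2 fold change 2.19; adjusted p = 0.218). Vldlr lost its call without wild type replicate 1 (2.14; 0.144) or 3 (2.08; 0.0621) and without SKO replicate 1 (2.91; 0.0558), 2 (2.5; 0.137) or 3 (2.48; 0.135), and stood at 6.47 without wild type replicate 2. It also lost its call with library totals (adjusted p = 0.08), robust fitting in edgeR (0.128), DESeq2 (0.257) and the GC content and length correction (0.0767). DESeq2 did not call Gk2 (0.27) or Als2cr12 (0.115), limma-voom did not call Gja1 (0.0868), and limma-voom with sample weights did not call Gja1 (0.121) or Prodh2 (0.0857). Gk2 lost its call without wild type replicate 1 (−3.10; 0.0808) or 3 (−3.0; 0.066) and without SKO replicate 1 (−2.58; 0.0584) or 2 (−2.61; 0.0725). Slc1a4, Als2cr12 and Gk2 each had counts in a single library of their lower group, and without it (wild type replicate 1, SKO replicate 1 and SKO replicate 3) their fitted values were 9.32, −9.37 and −9.49.

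**Figure D1:**
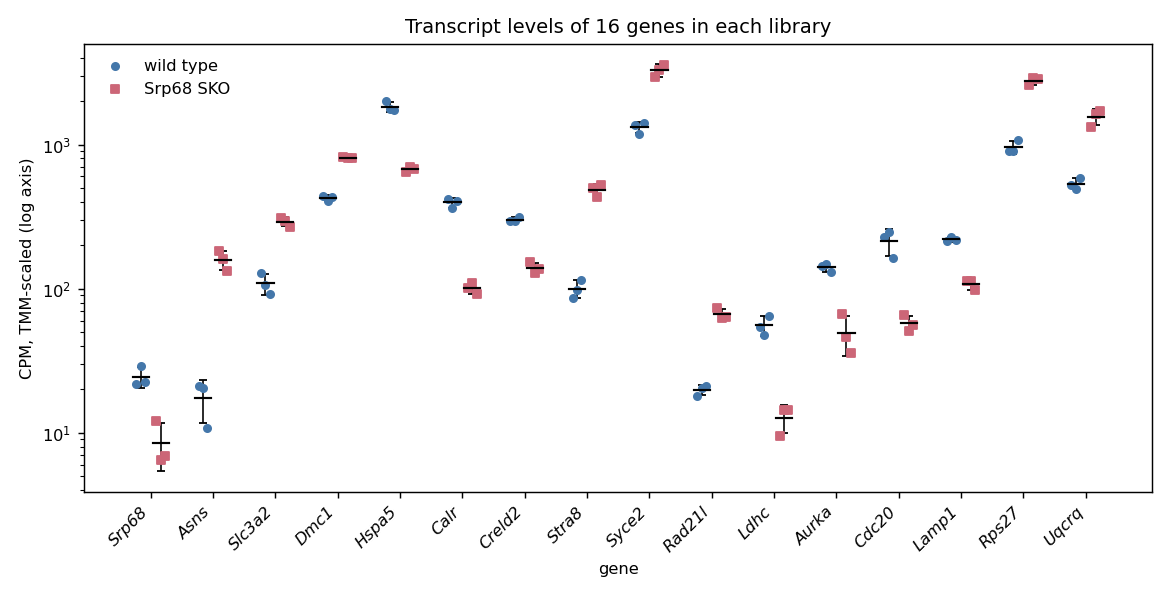
Transcript levels of 16 genes in each library, in TMM-scaled CPM on a log axis, with blue circles for the 3 wild type and red squares for the 3 Srp68 SKO libraries. Black lines mark the mean and 1 SD of each genotype; Srp68 lay lower in every SKO library, Asns (158 against 17.4 CPM) higher, and Hspa5 (675 against 1835 CPM) lower.

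More genes of the integrated stress response rose than fell. This pathway, which acts through the transcription factors ATF4 and CHOP, had 10 of 22 tested members higher, 2 lower and 10 not passed, with a median log2 fold change of 0.61 that was the same with Chac1 set to its bound. Adjusted over the list alone, 12 were higher and 3 lower. Beside Chac1, Slc7a11 and Asns, Slc3a2, the heavy chain shared by several amino acid transporters, rose from 109 ± 18.5 to 291 ± 20.4 CPM (edgeR adjusted p = 5.32e-06). The gene for CHOP itself, Ddit3, named after its values were seen, rose from 29.1 ± 6.19 to 89.6 ± 4.47 CPM, while Atf4, also named after its values were seen, was at 55.0 ± 8.95 and 73.5 ± 10.8 CPM (edgeR adjusted p = 0.0703). Camera with its preset correlation gave an adjusted p of 1.22e-05 for the list; it was 0.185 with an estimated correlation. After removal of each library's trend with GC content and length the list median was 1.01, and Atf4 passed with a log2 fold change of 0.93 in place of 0.42 (edgeR adjusted p = 0.000589). Atf4 also passed with upper-quartile scaling (adjusted p = 0.0494), a filter of 5 CPM (0.0462), DESeq2 (0.0401) and limma-voom with sample weights (0.0486), and stood at 0.16 with library totals (0.529).

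ER chaperone and ER-associated degradation genes moved in both directions, with more lower than higher. Of 26 tested members, 12 were lower, 5 higher and 9 not passed (adjusted over the list alone, 13 lower and 6 higher), with a median log2 fold change of −0.37. Hspa5, which encodes the ER chaperone BiP, fell from 1835 ± 146 to 675 ± 26.9 CPM (edgeR adjusted p = 4.49e-07). Calr, the calcium-binding lectin chaperone calreticulin, fell from 396 ± 32.3 to 100 ± 9.26 CPM (2.66e-07), and Creld2 from 301 ± 12.8 to 139 ± 12.7 CPM (8.33e-06). The membrane lectin chaperone Canx (log2 fold change 1.04), the chaperone Hsp90b1 (0.85) and Herpud1 (1.73), a component of ER-associated degradation, were among the 5 members that rose, and are named after their values were seen. Camera gave an adjusted p of 0.00299 for the list, and 0.456 with an estimated correlation.

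Among SRP genes, the transcripts of the small subunits rose while that of the direct partner of Srp68 was level in these data. Of 9 tested members of the SRP and SRP receptor list, 3 were higher, 1 (Srp68) lower and 5 not passed, with the same counts adjusted over the list alone (median log2 fold change 0.26). Srp14 rose from 826 ± 73.9 to 1411 ± 83.6 CPM (edgeR adjusted p = 5.35e-05), Srp19 from 457 ± 47.5 to 710 ± 52.7 CPM (0.000449) and Srp9 from 733 ± 80.8 to 1138 ± 128 CPM (0.000643). With library totals in place of TMM, the log2 fold changes of these 3 genes were 0.51, 0.37 and 0.37 in place of 0.77, 0.64 and 0.63, and their calls held. Srp72, whose protein binds Srp68 directly, was at 64.4 ± 9.01 and 63.7 ± 10.0 CPM (log2 fold change −0.02, SE 0.16; edgeR adjusted p = 0.956). The receptor genes Srpr (0.28) and Srprb (−0.36), and Srp54c (0.26) and Srp54a (0.16), did not pass. Camera gave an adjusted p of 0.215 for the list, and 0.456 with an estimated correlation. The list passed in fry of limma (0.00317), and its median relative to all genes was 0.14 after the GC content and length correction in place of 0.28.

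Other steps of entry into the ER and the secretory pathway showed changes in both directions. Of 17 translocon and signal peptidase genes, 7 were higher, 5 lower and 5 not passed (adjusted over the list alone, 9 higher and 6 lower; median log2 fold change 0.28; camera adjusted p = 0.109). The translocon subunit genes Sec61b and Sec61g rose from 314 ± 17.5 to 609 ± 48.7 CPM and from 366 ± 30.9 to 684 ± 65.6 CPM, while Ssr2, a subunit of the translocon-associated complex, fell from 734 ± 136 to 362 ± 38.2 CPM. Of 21 genes of SRP-independent targeting and insertion, 6 were higher, 8 lower and 7 not passed (adjusted over the list alone, 6 higher and 10 lower; median −0.30; camera adjusted p = 0.350). In that list Emc10 (60.3 ± 5.86 to 13.1 ± 5.01 CPM) and Asna1, the ATPase that delivers tail-anchored proteins (52.7 ± 12.5 to 16 ± 1.87 CPM), fell, and Emc2 rose (375 ± 54.6 to 700 ± 94.2 CPM). Of 24 N-glycosylation genes, 4 were higher, 5 lower and 15 not passed (adjusted over the list alone, 5 higher and 7 lower; median −0.03; camera adjusted p = 0.384), with decreases of Ddost (340 ± 19.8 to 136 ± 27.7 CPM) and Alg1 (25.1 ± 4.21 to 7.61 ± 0.503 CPM) and an increase of Krtcap2 (200 ± 24.5 to 362 ± 24.0 CPM). Of lysosomal protein genes, 8 of 21 were lower, 0 higher and 13 not passed, with the same counts adjusted over the list alone (median −0.70; camera adjusted p = 0.0138, and 0.185 with an estimated correlation). Lamp1, a major lysosomal membrane protein, fell from 220 ± 8.82 to 108 ± 9.27 CPM, the protease gene Ctsb from 43.7 ± 10.1 to 17.0 ± 4.65 CPM and Npc2, a cholesterol carrier, from 105 ± 12.5 to 64.3 ± 8.46 CPM. After the GC content and length correction, the lysosomal median was −0.44 and the list no longer passed (camera adjusted p = 0.184), and Ssr2, Ddost, Alg1 and Npc2 stood at −0.60, −0.84, −1.11 and −0.44 in place of −1.02, −1.32, −1.72 and −0.70, with their calls held. Relative to all genes, the translocon median was 0.17 after the correction in place of 0.31. That of SRP-independent targeting, −0.27, stood at −0.10 after it, −0.11 with a filter of 5 CPM, −0.16 without wild type replicate 3 and −0.14 without SKO replicate 3, and that of N-glycosylation, near 0 in the main test, at −0.12 after it and −0.13 without wild type replicate 2. The last of these lists passed in fry of limma (0.0281), as did SRP-independent targeting (0.0144).

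Most tested members of the meiotic entry list, and most tested genes of the synaptonemal complex and meiotic cohesin, rose. The entry list shares Sycp3 and Rec8 with the synaptonemal list and Prdm9 with the recombination list, so it does not hold entry regulators alone. Of 15 members of the entry list, 11 were higher, 1 lower and 3 not passed (adjusted over the list alone, 11 higher and 2 lower), with a median log2 fold change of 0.60. Stra8, the retinoic acid responsive factor required for meiotic initiation, rose from 99.9 ± 14.1 to 486 ± 50.2 CPM (edgeR adjusted p = 2.66e-07). Tex15 rose from 734 ± 92.1 to 1618 ± 164 CPM and Ccnb3 from 249 ± 40.5 to 575 ± 63.5 CPM. Of 16 synaptonemal complex and meiotic cohesin genes, 11 were higher, 2 lower and 3 not passed, with the same counts adjusted over the list alone (median 0.80). Syce2 and Tex12, both of the central element of the complex, rose from 1321 ± 121 to 3272 ± 328 CPM and from 991 ± 124 to 2407 ± 409 CPM, and the cohesin gene Rad21l from 19.8 ± 1.56 to 66.3 ± 6.28 CPM. Camera gave adjusted p = 1.00e-06 for the entry list and 1.02e-08 for the synaptonemal list, which were 0.185 and 0.174 with an estimated correlation. The medians were 0.23 and 0.29 after the GC content and length correction, with both lists still past the threshold, and Tex15 and Tex12 stood at 0.70 and 0.49 in place of 1.14 and 1.28, with their calls held.

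Recombination genes moved in both directions, and most tested markers of the later pachytene stage fell. Of 30 double-strand break and recombination genes, 13 were higher, 6 lower and 11 not passed (adjusted over the list alone, 14 higher and 7 lower; median log2 fold change 0.34; camera adjusted p = 0.103; fry adjusted p = 0.0281). The meiotic recombinase gene Dmc1 rose from 426 ± 17.9 to 809 ± 11 CPM (edgeR adjusted p = 8.46e-06), whereas 1700102P08Rik, the crossover factor gene also called Spo16, fell from 237 ± 7.21 to 117 ± 2.45 CPM and Cntd1, a crossover maturation gene, from 43.1 ± 6.86 to 9.47 ± 1.64 CPM. Of the exon length of Cntd1, 70.2% overlaps Becn1 on the opposite strand, so its counts are uncertain. Of 22 pachytene markers, 14 were lower, 1 higher and 7 not passed, with the same counts adjusted over the list alone (median −1.03). Ldhc, the germ cell lactate dehydrogenase, fell from 55.7 ± 8.72 to 12.7 ± 2.84 CPM (edgeR adjusted p = 9.95e-06), the kinase gene Aurka from 140 ± 9.57 to 49.4 ± 15.5 CPM and the chaperone gene Clgn from 44.7 ± 10.3 to 14.0 ± 1.38 CPM. Camera gave an adjusted p of 1.14e-06 for the pachytene list, and 0.174 with an estimated correlation. Of 6 tested spermatid markers, Odf2 (log2 fold change −0.63) and Spaca1 (−0.82) were lower, Tnp1 (3.02) higher and 3 not passed, with the same counts adjusted over the list alone. The spermatid list had a median of −0.30 and a mean of 0.28, and camera put it lower with an adjusted p of 0.718. Its median relative to all genes, −0.27, turned to 0.17 without wild type replicate 2, stood between −0.71 and −0.61 without wild type replicate 1 or any SKO replicate, at −0.52 with no low-count filter, at −0.03 in limma-voom and at −0.04 after the correction for GC content and length. Tnp1 was at 0.343 ± 0.304 and 2.88 ± 0.74 CPM and lost its call without wild type replicate 1 (adjusted p = 0.0597), SKO replicate 1 (0.118), 2 (0.0633) or 3 (0.0867), after the GC content and length correction (0.0834) and in limma-voom with sample weights (0.0565). Odf2 lost its call without wild type replicate 2 (0.0528), and Spaca1 without wild type replicate 3 (0.149), SKO replicate 2 (0.118) or SKO replicate 3 (0.0928).

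X-linked genes were higher in SKO spermatocytes relative to autosomal genes. The 614 tested X-linked genes had a median log2 fold change of 0.39 against −0.05 for 12802 autosomal genes, a difference of 0.44 (bootstrap SE 0.0327 over genes). Of the X-linked genes, 169 (27.5%) were higher and 23 (3.75%) lower, while 13.4% of autosomal genes were higher and 14.9% lower. Camera on the X-linked set gave p = 3.49e-07, and p = 0.00579 with an estimated correlation. After the GC content and length correction the difference was 0.23 (SE 0.0273), the lowest of 18 alternatives, which ran up to 0.50 and all kept the call.

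Markers of spermatogonia, the mitotic germ cells that precede meiosis, gave no list call. Of 11 tested markers of undifferentiated spermatogonia, 2 were higher and 9 not passed (median log2 fold change 0.16; camera adjusted p = 0.439), with Taf4b at 138 ± 11.2 and 280 ± 48.5 CPM and Tspan8 at a log2 fold change of 1.58. Of 14 markers of differentiating spermatogonia, 1 was higher, 3 lower and 10 not passed (median −0.08; camera adjusted p = 0.716), with Rhox13 higher (0.86) and Uchl1 (−0.86) and Sohlh2 (−0.79) lower. The counts adjusted over the list alone were the same for both lists. Tspan8 lost its call without SKO replicate 1 (adjusted p = 0.0682) or 3 (0.0647) and after the GC content and length correction (0.065), where Uchl1 stood at −0.47 with its call held. Relative to all genes, the undifferentiated median, 0.19, stood at 0.63 without wild type replicate 1, 0.35 without SKO replicate 3, 0.52 with no low-count filter, 0.38 in limma-voom and 0.54 after the correction, and turned to −0.22 without SKO replicate 1, −0.03 without wild type replicate 3 and −0.08 with a filter of 5 CPM. The differentiating median, −0.05, turned to 0.10 without wild type replicate 2, 0.07 without SKO replicate 2 and 0.31 after the correction, and stood at −0.11 without wild type replicate 3, −0.03 without SKO replicate 3, −0.10 in limma-voom with sample weights and −0.13 with no low-count filter.

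More mitotic cell cycle and piRNA pathway genes fell than rose. Of 25 mitotic genes, 10 were lower, 3 higher and 12 not passed (adjusted over the list alone, 10 lower and 4 higher; median log2 fold change −0.32; camera adjusted p = 0.0194, and 0.482 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell from 213 ± 44.8 to 57.5 ± 7.45 CPM (edgeR adjusted p = 3.06e-06), Ccnb1 from 423 ± 49.7 to 215 ± 13.7 CPM and Cdk1 from 281 ± 37.9 to 154 ± 10.6 CPM. After the GC content and length correction the mitotic median was −0.11 and the list no longer passed (camera adjusted p = 0.0879). Of 17 genes of the piRNA pathway, which silences retrotransposons in germ cells, 8 were lower, 1 higher and 8 not passed (adjusted over the list alone, 9 lower and 1 higher; median −0.52; camera adjusted p = 0.0193, and 0.185 with an estimated correlation). Mael fell from 816 ± 18.0 to 518 ± 45.8 CPM, Tdrd5 from 26.8 ± 4.66 to 8.59 ± 1.68 CPM and Tdrd9 from 36.5 ± 1.26 to 17.6 ± 2.37 CPM. Without wild type replicate 3 the piRNA list no longer passed (camera adjusted p = 0.0598).

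Cytosolic ribosomal protein genes rose in SKO spermatocytes, with 70 of 82 higher, 1 lower and 11 not passed (adjusted over the list alone, 71 higher and 2 lower; median log2 fold change 0.81). Rps27 rose from 957 ± 101 to 2778 ± 170 CPM (edgeR adjusted p = 4.49e-07), Rps19 from 1166 ± 76.3 to 2850 ± 72.2 CPM and Rpl35 from 597 ± 32.9 to 1567 ± 99.0 CPM. Ribosomal protein genes share sequence with many processed pseudogenes, and 66.2% of the exon length of Rpl35 overlaps Wdr38 on the opposite strand, so single-gene values are uncertain. Nuclear-encoded subunits of oxidative phosphorylation also rose, with 55 of 74 higher, 11 lower and 8 not passed (adjusted over the list alone, 56 higher and 14 lower; median 0.53). Uqcrq of complex III rose from 535 ± 46.2 to 1560 ± 202 CPM (edgeR adjusted p = 1.02e-06), Ndufa6 of complex I from 289 ± 28.1 to 655 ± 59.1 CPM and Cox7b of complex IV from 43.8 ± 5.66 to 118 ± 5.07 CPM. Camera gave adjusted p = 4.75e-54 for the ribosomal list and 6.93e-15 for the oxidative phosphorylation list, which were 0.174 and 0.186 with an estimated correlation. The 13 mitochondrially encoded genes had a median of 0.09 and 0 calls in edgeR's quasi-likelihood test (1 at an unadjusted p under 0.05, 1 call in DESeq2 and 1 in limma-voom; camera adjusted p = 0.628). That list turned over after the GC content and length correction, with a median of −0.63, 11 members lower and a camera adjusted p of 4.54e-07 (adjusted p = 0.0861 with an estimated correlation). The corrected fit differs from the main one only by the trends it subtracts, so this turn is by itself no sign of a fall. Relative to all genes, its median, 0.12, stood at 0.24 without wild type replicate 1, and at 0.03, 0.07 and 0.06 without wild type replicates 2 and 3 and SKO replicate 3.

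Other stress and homeostasis groups gave no list call in the main test. Of 22 apoptosis and p53 target genes, 7 were lower, 1 higher and 14 not passed (adjusted over the list alone, 7 lower and 2 higher; median log2 fold change −0.48; camera adjusted p = 0.0976). The apoptosis list passed with no low-count filter (camera adjusted p = 0.0143, and 0.19 with an estimated correlation) and in fry of limma (0.0281). Its median relative to all genes, −0.45, stood at −0.18 without SKO replicate 2, −0.24 without SKO replicate 1, −0.27 without wild type replicate 3, −0.30 without SKO replicate 3 and −0.69 with a filter of 5 CPM, none with a call. The p53 target Phlda3 fell from 8.27 ± 2.38 to 0.970 ± 0.38 CPM and the cell death genes Bad and Bax from 39.5 ± 1.53 to 12.8 ± 2.42 CPM and from 83.4 ± 29.6 to 35.3 ± 3.43 CPM. Corrected for GC content and length, Bad and Bax stood at −1.03 and −0.60 in place of −1.62 and −1.24, and 20.5% of the exon length of Bad overlaps Gpr137 on the opposite strand. Of 31 proteasome genes, 9 were higher, 9 lower and 13 not passed (adjusted over the list alone, 10 higher and 11 lower; median −0.15; camera adjusted p = 0.716), with Psmb6 (0.71) and Psmb1 (0.56) higher and Psmd13 (−1.11) lower. Of 22 cholesterol synthesis genes, 2 were higher, 3 lower and 17 not passed, with the same counts adjusted over the list alone (median −0.14; camera adjusted p = 0.716), with Idi1 (0.61) higher and Nsdhl (−0.84) and Fdft1 (−0.69) lower. Of 12 cytosolic heat-shock genes, 2 were higher, 4 lower and 6 not passed, with the same counts adjusted over the list alone, and Hspe1 (0.75) was higher while Ahsa1 (−0.83) and Dnajb1 (−0.81) were lower. The heat-shock list had a median of 0.03 and a mean of 0.12, and camera put it lower with an adjusted p of 0.716. The 6 tested interferon-stimulated genes had 0 calls in edgeR's quasi-likelihood test (1 at an unadjusted p under 0.05, 0 calls in DESeq2 and 0 in limma-voom; median 0.22; camera adjusted p = 0.964). Fdft1 lost its call without wild type replicate 1 (adjusted p = 0.119), SKO replicate 2 (0.06) or SKO replicate 3 (0.0879) and after the correction (−0.36; 0.19), and Nsdhl without wild type replicate 2 (0.06) or SKO replicate 2 (0.0561). Corrected, Psmd13, Idi1 and Dnajb1 stood at −0.68, 0.41 and −0.40, and with library totals Psmb6, Psmb1, Idi1 and Hspe1 stood at 0.45, 0.30, 0.35 and 0.49, all with their calls held. Relative to all genes, the proteasome median, −0.12, stood at −0.20 with no low-count filter or without SKO replicate 1, −0.06 without SKO replicate 3 and 0.00 after the correction. The cholesterol median, −0.11, stood at −0.19 with no low-count filter, −0.18 without wild type replicate 3 and −0.02 without SKO replicate 2, and turned to 0.06 with a filter of 5 CPM and 0.01 after the correction. The interferon median, 0.25, stood at 0.07 without wild type replicate 1, 0.44 without SKO replicate 2, 0.13 in limma-voom and 0.39 after the correction, and turned to −0.04 without SKO replicate 3. The heat-shock median, 0.06, stood at 0.02 in limma-voom and after the correction, 0.04 without wild type replicate 3 or SKO replicate 3, and turned to −0.07 without wild type replicate 2 and −0.06 with a filter of 5 CPM.

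Of 12 immediate early genes, 3 were higher and 9 not passed (adjusted over the list alone, 2 higher; median log2 fold change 0.75; camera adjusted p = 0.103). Fos, a transcription factor induced within minutes by many stimuli, was at 2.21 ± 0.69 and 17.6 ± 0.274 CPM (edgeR adjusted p = 2.04e-05), Klf4 at 4.18 ± 0.605 and 13.2 ± 1.34 CPM (0.000928) and Fosb at 0.868 ± 0.303 and 3.39 ± 2.06 CPM (0.0477). Fosb lost its call when any single library was left out (adjusted p = 0.0731, 0.0871 and 0.107 without wild type replicates 1, 2 and 3, and 0.301 and 0.11 without SKO replicates 1 and 3), except SKO replicate 2. It also lost it with library totals (0.084), with no low-count filter (0.0628), in limma-voom (0.0939) and in limma-voom with sample weights (0.171). The list passed after the GC content and length correction (median 1.33; camera adjusted p = 0.00876), with library totals (0.0318) and with no low-count filter (0.0247). With an estimated correlation in camera these adjusted p-values were 0.272, 0.315 and 0.227, and in fry the list passed (0.0281). Its median relative to all genes, 0.78, stood at 1.18 without SKO replicate 1, with no call.

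**Figure D2:**
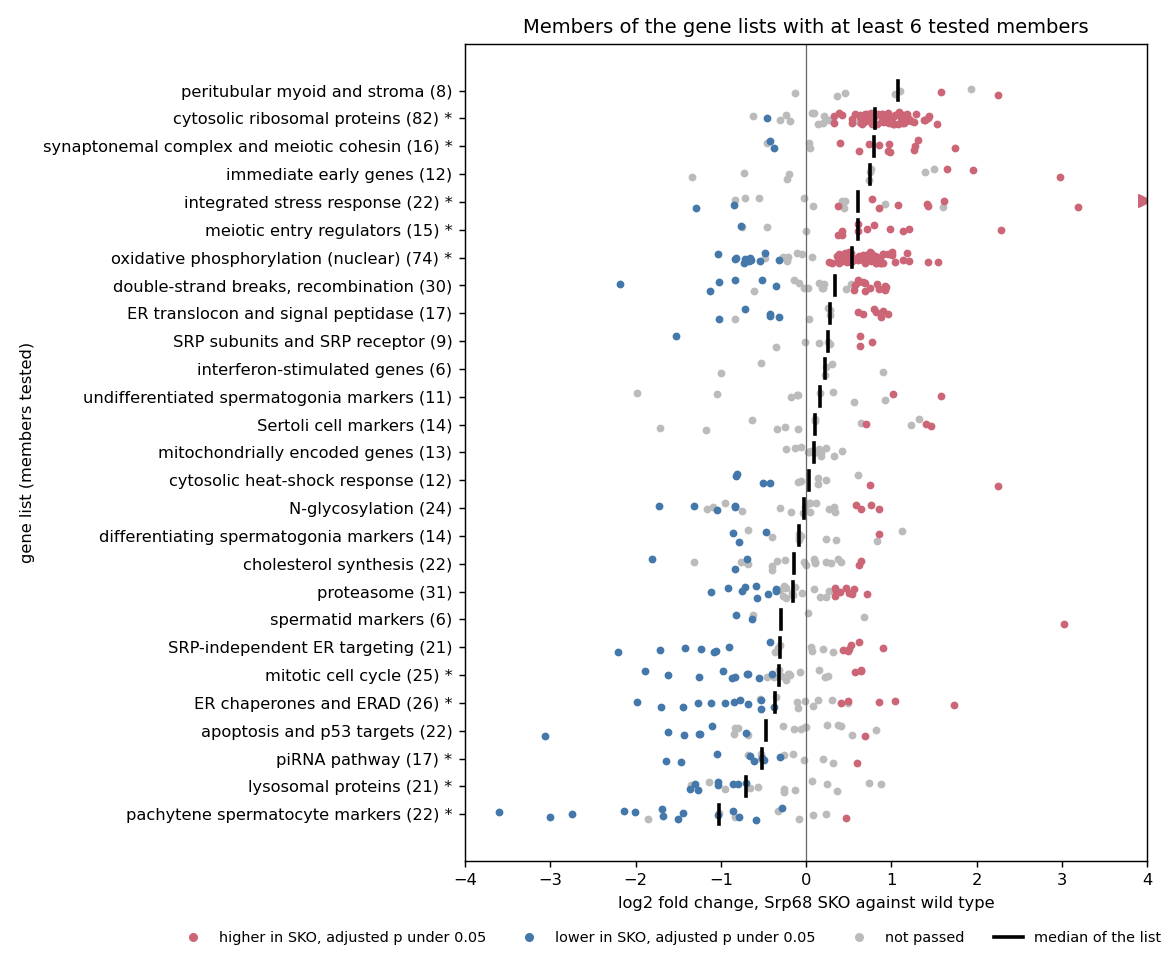
Log2 fold changes of the tested members of the 27 gene lists with at least 6 tested members, 1 point per gene, coloured by whether the gene was higher (red) or lower (blue) in Srp68 SKO at an adjusted p under 0.05 or did not pass (grey). Black bars mark list medians, from −1.03 for pachytene markers to 1.07 for myoid and stromal markers; asterisks mark camera adjusted p under 0.05, and 2 members beyond 4 are drawn as triangles at the edge.

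Several markers of somatic testis cells were higher in SKO libraries. Among those called, the Sertoli marker Ctsl (381 ± 33.3 and 618 ± 82.4 CPM) and the Leydig marker Fdx1 (131 ± 8.33 and 189 ± 18.1 CPM) were abundant in both genotypes, and the others had genotype means of up to 28.0 CPM, that of Rhox8 in SKO. Of 14 tested Sertoli cell markers, 3 were higher and 11 not passed (median log2 fold change 0.10; camera adjusted p = 0.553): Ctsl (0.70), Tmem37 (1.47) and Rhox8 (1.41). Of 3 tested Leydig cell markers, Fdx1 (0.53) and Igf1 (2.78) were higher and 1 did not pass (median 1.18; camera adjusted p = 0.103). The list has 12 members, and the rest had too few counts to be tested. Among them Cyp17a1, Cyp11a1 and Hsd3b6 were at 0 CPM in every library, while Hsd3b1 reached 2.77 CPM in SKO replicate 2. The abundant Fdx1 is therefore no clear sign of Leydig cells. Of 8 tested myoid and stromal markers, Acta2 (2.25) and Myl9 (1.58) were higher and 6 not passed (median 1.07; camera adjusted p = 0.148). Of 3 tested macrophage and leukocyte markers, Fcer1g (3.72) and Lyz2 (3.35) were higher and 1 did not pass (median 3.35; camera adjusted p = 0.694). Counts adjusted over the list alone were the same for these 4 lists. Of 2 tested endothelial markers, Egfl7 (−1.06) was lower and 1 did not pass, too few for a list test. The 4 tested erythroid markers had 0 calls in edgeR's quasi-likelihood test (1 at an unadjusted p under 0.05, 0 calls in DESeq2 and 2 in limma-voom; median 1.22; camera adjusted p = 0.249). SKO replicate 3 carried most of the macrophage signal, with Lyz2 at 25.2 CPM against 1.23 and 0.558 in the other SKO libraries and Fcer1g at 17.5 against 0.741 and 1.49 CPM.

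Without SKO replicate 3, Lyz2 (log2 fold change 0.04; adjusted p = 0.991), Fcer1g (1.17; 0.639), Rhox8 (0.68; 0.102), Acta2 (1.52; 0.114), Myl9 (1.16; 0.145), Igf1 (2.60; 0.105) and Egfl7 (−0.88; 0.13) lost their calls. These markers were also lost without other libraries: Lyz2 without wild type replicate 1 (0.16) or 2 (0.137), Fcer1g without wild type replicate 1 (0.0709) or 3 (0.0515), Myl9 without wild type replicate 1 (0.0749) or 2 (0.0528) or SKO replicate 2 (0.0533), Igf1 without wild type replicate 3 (0.053) or SKO replicate 1 (0.0565) or 2 (0.068), and Egfl7 without wild type replicate 1 (0.141) or 2 (0.0528) or SKO replicate 2 (0.125). After the GC content and length correction Egfl7 (−0.48 in place of −1.06; adjusted p = 0.344), Lyz2 (0.0633) and Igf1 (0.0606) also lost their calls. Lyz2 lost its call with library totals (0.0637), robust fitting in edgeR (0.2), limma-voom (0.297) and limma-voom with sample weights (0.373), and Fcer1g in DESeq2 (0.0852), limma-voom (0.219) and limma-voom with sample weights (0.263). Lyz2 stood at 5.16 without wild type replicate 3. Without wild type replicate 3, which held 146 CPM of summed erythroid markers against 3.02 and 5.66 CPM in the other wild type libraries, the erythroid list passed (camera adjusted p = 6.94e-05, and 0.325 with an estimated correlation). Without wild type replicate 2 the Leydig and myoid lists passed (0.0249 for both), and the myoid list also without SKO replicate 2 (0.0499), with library totals (0.0455) and with no low-count filter (0.0254). With an estimated correlation in camera these adjusted p-values were 0.399 for the Leydig list and 0.309, 0.474, 0.519 and 0.197 for the myoid list, and the Leydig list passed in fry (0.00523). Medians of these lists relative to all genes hung on single libraries. The Sertoli median, 0.13 with all libraries, turned to −0.47 without SKO replicate 3 and to −0.07 in limma-voom, and stood at 0.52 without wild type replicate 3 and 0.66 with a filter of 5 CPM. The Leydig median, 1.21, stood at 0.65 without wild type replicate 1, 0.71 without SKO replicate 3 and 2.2 without wild type replicate 2, and the myoid median, 1.1, at 0.59 without wild type replicate 1 and 1.83 without wild type replicate 2. The macrophage median, 3.38, turned to −0.10 without SKO replicate 3 and stood at 1.48 without wild type replicate 3, and the erythroid median, 1.25, at 0.60 without SKO replicate 2 and 4.6 without wild type replicate 3. With library totals Ctsl stood at 0.43 with its call held and Fdx1 at 0.27 without it (adjusted p = 0.0768), and 26.8% of the exon length of Ctsl overlaps Gm47123 on the opposite strand.

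Changes followed the GC content of transcripts and also varied with exon length. Across genes, which are not independent replicates, the log2 fold change fell with GC content (Spearman rho −0.34), from a median of 0.37 in the decile of lowest GC (38.8%) to −0.56 in the highest (59.1%). In the lowest decile, median deviations from the mean of all libraries were −0.16, −0.26 and −0.08 in the wild type libraries and 0.11, 0.25 and 0.28 in the SKO libraries. In the highest decile they were 0.26, 0.43 and 0.22 in wild type and −0.05, −0.25 and −0.38 in SKO. By exon length, the median log2 fold change was 0.50 in the shortest decile (633 bp), −0.24 in decile 3 (2161 bp) and 0.19 in the longest (12084 bp). This fall and rise left rho with exon length at −0.02. Wild type and SKO libraries tilted in opposite directions, so the GC trend is confounded with genotype. Whether it is technical or a real difference that tracks GC content cannot be told from these data, and the correction removes both. Once each library's trend with GC content and exon length was removed, 1426 genes were higher and 1680 lower, rho with GC content was −0.00, and 2472 of the 3838 calls (64.4%) held with the same direction. Srp68 then stood at −1.04 (edgeR adjusted p = 0.00848).

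**Figure D3:**
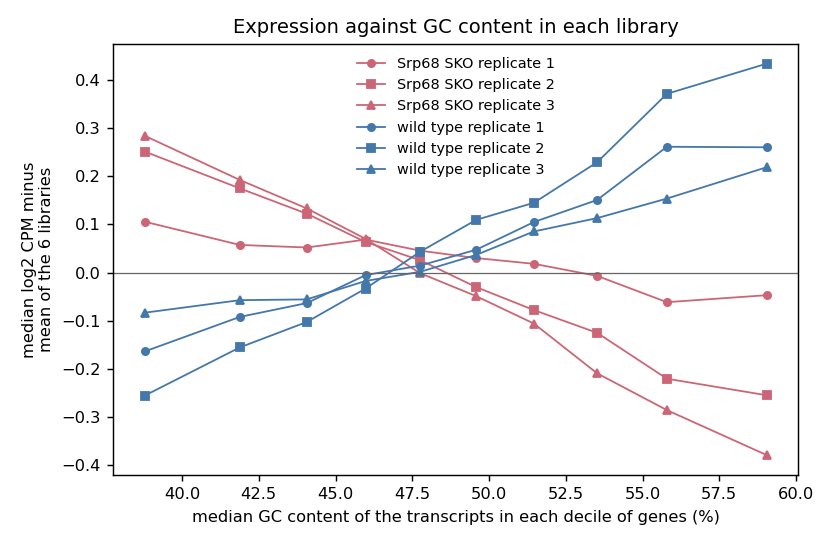
Median log2 CPM minus the mean of the 6 libraries, plotted against the median GC content in percent of each decile of tested genes, with 1 line per library (wild type blue, Srp68 SKO red). In the decile of lowest GC the wild type libraries lay between −0.26 and −0.08 and the SKO libraries between 0.11 and 0.28, and the order was turned over in the decile of highest GC.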

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

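Of the alternatives, only the correction for GC content and length, with and without the replicate block, was chosen after the data were seen. Srp68 was lower and passed the threshold in all 19 alternatives (log2 fold change −1.87 to −1.04, highest adjusted p 0.0109). The X-linked minus autosomal difference passed in all 18 in which it was computed (0.23 to 0.50). With library totals only, 1010 genes were higher and 3168 lower, against 1901 and 1937. A minimum of 2-fold left 521 higher and 1060 lower, an adjusted p of 0.01 left 1230 and 1142, and a test against a 1.5-fold change (glmTreat) left 423 and 648, all stricter by construction. Leaving out each library in turn gave 1361 to 1916 higher and 1373 to 1851 lower. DESeq2 called 2146 and 2106, with 525 adjusted p-values not given, limma-voom 1945 and 1777, and edgeR without a low-count filter 2016 and 2070.

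The count of 10 lists past the threshold was 17 in fry and 0 in camera with an estimated correlation (8 at an unadjusted p under 0.05). The 7 lists that fry, which does not compare a list with other genes, added to the 10 were the SRP, SRP-independent targeting, N-glycosylation, apoptosis, recombination, Leydig and immediate early lists. List tests were not run in DESeq2 or in edgeR with robust fitting. The mitochondrially encoded list turned over after the GC content and length correction, with a median relative to all genes of −0.60 (adjusted p = 4.54e-07), and with the replicate block added it stood at −0.57 (7.93e-08), against 0.12 without either; with an estimated correlation these adjusted p-values were 0.0861 and 0.325. The list was level in the main test, and the correction alone differs from it only by the trends it subtracts. The turn therefore reflects those trends, and whether they were rightly removed for these genes was not tested. That correction ended the calls of the mitotic and lysosomal lists, started that of the immediate early list, and gave 1426 genes higher and 1680 lower. The largest number of named genes lost their calls without SKO replicate 3 (14 of 95), and 9 each without wild type replicate 1 and SKO replicate 2, 6 each without the other libraries and 7 after the correction. None of the named genes changed direction in any alternative run. The first principal component carried 49.9% of the variance over the 500 most variable genes, against 46.4% over all tested genes.

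With the replicate block, 1976 genes were higher and 1991 lower, and with the block and the GC content and length correction together 1458 and 1696. The replicate numbers do not pair the libraries. Correlations of deviations between libraries of the same number were 0.0214, −0.0505 and 0.0391, and 2 of the 6 libraries correlated best with their own number. Depth limits genes near the floor, where 3 counts were 0.195 to 0.253 CPM. In simulated counts 48% of 2-fold changes were recovered, with 100 genes of any expression level changed at each fold. That is a far smaller share than the 28.5% of tested genes called here, so recovery in these data may differ.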

Other observations

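The tests of mitotic spermatogonia, of an earlier meiotic stage and of handling stress, the closer matches on expression, the tests of each list of a pair alone, and the correction for GC content and length, were chosen only after the results were seen, as were the genes singled out from the oxidative phosphorylation and integrated stress response lists and the predicted genes and receptor genes. The increase of oxidative phosphorylation genes did not extend to all subunits. The 11 members that fell included Uqcrc1 (310 to 152 CPM; log2 fold change −1.03; edgeR adjusted p = 0.000234) and Uqcrc2 (−0.54) of the complex III core, the ATP synthase subunit genes Atp5a1 (−0.67) and Atp5b (−0.64), and the complex II genes Sdha (−0.73), Sdhc (−0.48) and Sdhd (−0.66). Within the integrated stress response list, Phgdh, the first enzyme of serine synthesis, fell from 17.2 ± 1.06 to 7.02 ± 1.34 CPM (edgeR adjusted p = 0.00216), while Asns rose. With the GC content and length correction, Phgdh (−0.68; adjusted p = 0.079), Atp5a1 (−0.15; 0.374) and Atp5b (−0.31; 0.0772) no longer passed in edgeR, and Uqcrc1 and Sdhc stood at −0.63 and −0.32 with their calls held. With library totals Sdhc stood at −0.74. Of 20 tested Y-linked genes, 10 were higher and 1 lower.

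Counts of the predicted gene Gm10800 stood at 37.1, 29.0 and 83.6 CPM in the wild type libraries and at 215, 536 and 374 CPM in the SKO libraries, and Gm10722 at 1.47, 2.02 and 4.13 against 10.2, 28.1 and 20.1 CPM. Summed olfactory and vomeronasal receptor genes stood at 58.6, 38.3 and 42.9 CPM in wild type and 38.4, 55.6 and 33.0 CPM in SKO libraries.

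The comparison of all genes was set against the other splits of the 6 libraries. The real split gave 3838 calls and the highest of the other 9 gave 0 in edgeR (5252 and 515 genes at an unadjusted p under 0.05). Only 1 of 10 splits gave as many calls as the real one, and 10 splits are too few for a share under 0.05. Every other split mixed both genotypes in each group, so a genotype difference itself widens the spread there and holds calls down. The contrast is therefore no measure of chance.

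Of pachytene markers 14 of 22 were lower and 1 higher in SKO cells, and of synaptonemal complex and meiotic cohesin genes 11 of 16 were higher and 2 lower. A bias by GC content and length as the whole source is argued against by the corrected difference between the list medians, 1.30 (SE 0.322) against 1.82 uncorrected. That rests on the pachytene list, which lay at −0.98 (SE 0.301) relative to all genes after the correction and −0.998 before it. The synaptonemal list fell from 0.82 to 0.32 (SE 0.135), so most of its change followed GC content and length, and whether that bias is its whole source stays open. A candidate explanation is that the sorted SKO cells stood at an earlier meiotic stage, as X-linked genes, which are silenced as spermatocytes reach pachytene, stayed above autosomal genes after the correction by 0.23 (SE 0.0273). Spermatogonia, which precede that silencing, would raise X-linked genes as well, so the difference does not single out an earlier meiotic stage. More mitotic spermatogonia among the sorted SKO cells stay open: the mitotic cell cycle list lay at −0.0826 (SE 0.0984) relative to all genes after the correction and −0.29 (SE 0.118) before it, while markers of undifferentiated and differentiating spermatogonia lay at 0.54 (SE 0.223) and 0.31 (SE 0.147) after it. A direct effect of Srp68 loss on these genes and a different stage composition of the sorted cells cannot be separated in bulk libraries of 1 time point.

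Of ER chaperone genes 12 of 26 were lower and 5, among them Canx, Hsp90b1 and Herpud1, higher, and of integrated stress genes 10 of 22 were higher and 2 lower; with an estimated correlation camera in limma called neither list (adjusted p = 0.456 and 0.185). The difference between the list medians was 1.32 (SE 0.306) after the GC content and length correction and 0.98 before it, which argues against that bias as the whole source. The integrated stress list lay at 1.04 (SE 0.248) relative to all genes after the correction and 0.64 before it. For the ER chaperone list, at −0.28 (SE 0.189) and −0.34, the spread leaves the bias open. Handling stress during dissociation may have added to it and stays open: 3 of 12 immediate early genes were higher, and the list lay at 0.78 (SE 0.455) relative to all genes. After the correction 4 were higher and the list lay at 1.36 (camera adjusted p = 0.00876 in limma, and 0.272 with an estimated correlation). A hypothesis that stays open is an ATF4 response without a matching rise of the ER chaperone list, whose genes lie under ATF6 and XBP1. The list was split, as Hspa5 and Calr fell while Hsp90b1 and Herpud1 rose. Protein levels would be needed to test the hypothesis.

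Cytosolic ribosomal protein genes were higher in SKO libraries. Their mRNAs are short and abundant, so a better recovery of such transcripts might raise them together. Of 10000 lists matched on GC content, exon length and expression, the median list stood at 0.25. The upper bound of the central range was 0.39 and the highest list 0.53, against 0.81 for ribosomal protein genes. This argues against a rise shared by other protein-coding genes of like GC content, exon length and expression as the whole source. Nuclear-encoded oxidative phosphorylation genes, which rose too (median 0.53), were left out of the genes drawn from. Leaving them out may have lowered the range of the matched lists. Exon length was that of all annotated exons of a gene together, not of its mRNA. Short mRNAs were thus not matched as such, and their better recovery stays open. The matched lists were less abundant (median 539 CPM against 776 CPM), and 2 closer matches on expression were tried. They reached 660 and 732 CPM, the latter at the cost of a longer exon length (2076 against 1776 bp), and put the upper bound at 0.45 and 0.47 and the highest list at 0.59 and 0.57. Reads shared with pseudogenes were not tested, and no biological explanation was tested.

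The hypothesis that mRNAs of proteins predicted to need SRP are lower in SKO cells was tested on medians and not borne out. The 3539 predicted clients had 412 genes higher (11.6%) and 554 lower (15.7%), and the 7780 other protein-coding genes 1251 (16.1%) and 1297 (16.7%). Clients were thus less often higher, with similar shares lower. The 883 clients with an N-terminal signal only had 10.5% higher and 17.6% lower, with a median log2 fold change of −0.17, and −0.03 after the GC content and length correction. The medians of all clients and of the other protein-coding genes differed by −0.00181 (bootstrap SE 0.0181) after the GC content and length correction and by −0.03 before it. In limma, camera on the predicted clients gave an unadjusted p of 0.461 after the correction. The prediction took 95.2% of lysosomal and 88.2% of translocon genes as clients and 6.45% of proteasome and 8.64% of ribosomal protein genes.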
